A study of Gallus gallus with 5 samples.

How the data were processed

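Total RNA came from 5 DT40 cultures, 1 for each of WT, DKO, DKO+H2A.Z.1, DKO+5KR-H2A.Z and DKO+H2A-H2A.Z. Per the labels' protocols, cells were grown with tetracycline at 2 µg/ml for 72 hours, RNA was extracted on columns, and 100 ng was labelled with cyanine 3 for one-colour Agilent arrays. Images were read with Agilent Feature Extraction 11.5.1.1, per the file headers. The deposited scanner files give, for each spot, a processed signal, which is a fluorescence intensity on a linear scale after background subtraction, with the median spot and background intensity and quality flags, per the file headers. The authors' value table holds an intensity on the same linear scale: on each array it equals the processed signal times 1 constant, 1.032 for DKO+H2A.Z.1 to 1.227 for DKO, found from spots of at least 1000. Its values are neither logarithms nor centred, its column medians run from 92.1 to 121.7, and how the authors set the constant is not given in the sources used here.

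Processed signals were put on the log2 scale and the 75th percentile of each array's non-control spots was subtracted. Spots marked as non-uniform or as population outliers, between 2 and 37 per array, were left out, and spots of 1 probe were averaged. Probes were named through the RefSeq transcript accession in the files, without its version, matched to a gene table of assembly GRCg7b: 11935 of 43603 probes matched, and 1141 spots with a RefSeq accession did not. The files' own annotation is for galGal3, so no coordinates are given and the table served for names and for which genes neighbour each other. Of the 5382 genes, 3624 had more than 1 probe; each gene was read from the probe with the highest mean, and disagreement between probes is stated where it occurs. A gene entered a comparison when well above background on at least 1 of the arrays compared. Where all probes of a gene were not well above background on 1 array, the fold is a bound, from the higher of the lowest signal well above background on that array and the gene's own. Such a bound holds for the main processing. Differences were smaller under some alternatives, and for some genes they fell under 2-fold, as given below. For MPST in DKO+H2A.Z.1 minus WT the smallest was 5.28 on the log2 scale. For LAMB4 in DKO+5KR-H2A.Z minus DKO+H2A.Z.1 it was 1.38.

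With 1 array per group no test was possible. Counts of genes at least 2-fold apart, shares and correlations describe these arrays, whose number limits the precision. The 29 gene lists were fixed before the data were examined; 26 had at least 5 measured members, and each list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean signal. A gene apart between DKO and WT was called restored in a line when its level lay past the midpoint (0.5) from DKO towards WT. The 6 main comparisons were DKO minus WT, DKO+H2A.Z.1 minus DKO, DKO+H2A.Z.1 minus WT, each mutant line minus DKO+H2A.Z.1, and DKO+5KR-H2A.Z minus DKO+H2A-H2A.Z. Genes to be named were fixed by rule before the data were examined: for DKO, the 12 genes up and 12 down furthest, by the smaller difference, from both WT and DKO+H2A.Z.1; for DKO+H2A.Z.1 minus WT and the 3 comparisons of mutant lines the 12 largest in each direction among genes well above background on both arrays; the 4 largest bounds in each direction; up to 4 members of each list past 2-fold; H2AFZ; and the 8 in each direction that best parted the arrays by intact H2A.Z. The text prints a part of these, chosen after their values were seen, and gives the number of alternative settings with a gene past 2-fold where more than 1 of them lost it. For comparisons that share an array, 100 simulations of unchanged arrays gave the likeness to be had without any effect, as they did for restoration and for genes apart from both references; their noise was estimated from the difference between DKO+H2A-H2A.Z and DKO+H2A.Z.1.

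The steps were tested on simulated data with known answers. For DKO minus WT, with 4400 genes, 3 of 50 genes changed 1.5-fold, 26 of 50 changed 2-fold, 50 of 50 changed 3-fold and 50 of 50 changed 4-fold were called, and 39 of 4200 unchanged genes were. Of 200 lists of unchanged genes, 10 fell outside the central 95%. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, median centring, cyclic loess, stricter and looser filters on dim probes, the authors' value table, the median over a gene's probes, marked spots kept, thresholds of 1.5-fold and 3-fold, restoration asked within 1.5-fold of WT or for genes apart from both references, and random lists not matched on signal. Normexp was planned on the mean spot signal, which the files used do not hold, so it was run on the median spot and background intensity. Scaling to the 8 spike-in probes well above background and leaving out the genes of 1 chromosome were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with limma 3.58.1 in R 4.3.3 for normexp, quantile and cyclic loess normalization and matplotlib 3.10.9 for plots.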

Results

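Gene expression was measured on 5 one-colour oligonucleotide arrays, each hybridised with RNA from 1 culture of DT40, a chicken B cell line that came from a lymphoma of the bursa. The lines were wild type (WT), a double knockout of the genes for both forms of the histone variant H2A.Z (DKO), and 3 lines made from the DKO by stable expression of H2A.Z.1, of the H2A.Z.1 mutant called 5KR-H2A.Z, or of the mutant called H2A-H2A.Z (DKO+H2A.Z.1, DKO+5KR-H2A.Z and DKO+H2A-H2A.Z). Every culture was kept in 2 µg/ml tetracycline for 72 hours, which switches off a repressible H2A.Z.1 transgene. The series title places the question in the N-terminal tail of H2A.Z. Each line was measured on 1 array, so no difference here has a replicate check or a p-value, and each describes these arrays. The labels of 1 array conflict: its title and source name call it the DKO, while its description and genotype field repeat the words for the line that expresses H2A.Z.1. It is called DKO here after its title.

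Of 43803 spots that are not controls, between 29137 on the DKO array and 30574 on the WT array were well above background, and none was saturated. Replicate spots within an array had a median SD between 0.0477 and 0.0610 on the log2 scale. A gene name was available for 11935 of 43603 probes, standing for 5382 genes, of which 4110 were well above background on all 5 arrays. WT, DKO and DKO+H2A.Z.1 lay on 1 slide and both mutant lines on another. Differences between a mutant line and WT, DKO or DKO+H2A.Z.1 therefore cannot be told apart from a difference between the slides, wherever they appear below. Within a slide, WT, DKO and DKO+H2A.Z.1 were compared with each other, and the mutant lines with each other.

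The targeted gene was read by 2 probes for H2AFZ (NM_001031374), which encodes H2A.Z.1; no named probe stood for the gene of the other form. In the DKO and the 3 lines made from it, probe A_87_P037084 was 24.8-fold to 33.4-fold lower than in WT and probe A_87_P194348 was 82.6-fold to 99.0-fold lower. The lower level of H2AFZ separated WT from all lines made from the DKO. Both probes were still well above background on every array, so signal for H2AFZ remained in these lines. There A_87_P037084 stood at 0.81 to 1.24 and A_87_P194348 at -0.46 to -0.20. These log2 values are relative to the percentile subtracted from each array. Which part of the transcript each probe covers was not known here, so these probes check neither the complementing constructs nor the conflicting label of the DKO array.

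The largest contrast among the planned comparisons was that between DKO and WT, with 185 genes at least 2-fold higher and 488 at least 2-fold lower in DKO out of 4399. DKO+H2A.Z.1 differed from DKO by 351 genes higher and 114 lower, and from WT by 85 higher and 173 lower. The mutant lines lay closer to DKO+H2A.Z.1, with 81 genes higher and 34 lower in DKO+5KR-H2A.Z and 77 higher and 48 lower in DKO+H2A-H2A.Z, and they differed from each other by 70 genes higher and 94 lower in DKO+5KR-H2A.Z. Counted over all probes, named or not, 5328 of 30963 differed between DKO and WT and 1088 of 30437 between DKO+5KR-H2A.Z and DKO+H2A.Z.1. With a background correction that damps dim probes (normexp) the gene counts dropped to 379 for DKO against WT, 242 for DKO+H2A.Z.1 against DKO, 97 for DKO+H2A.Z.1 against WT, 17 and 36 for the mutant lines against DKO+H2A.Z.1 and 45 between the mutant lines.

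**Figure D1:**
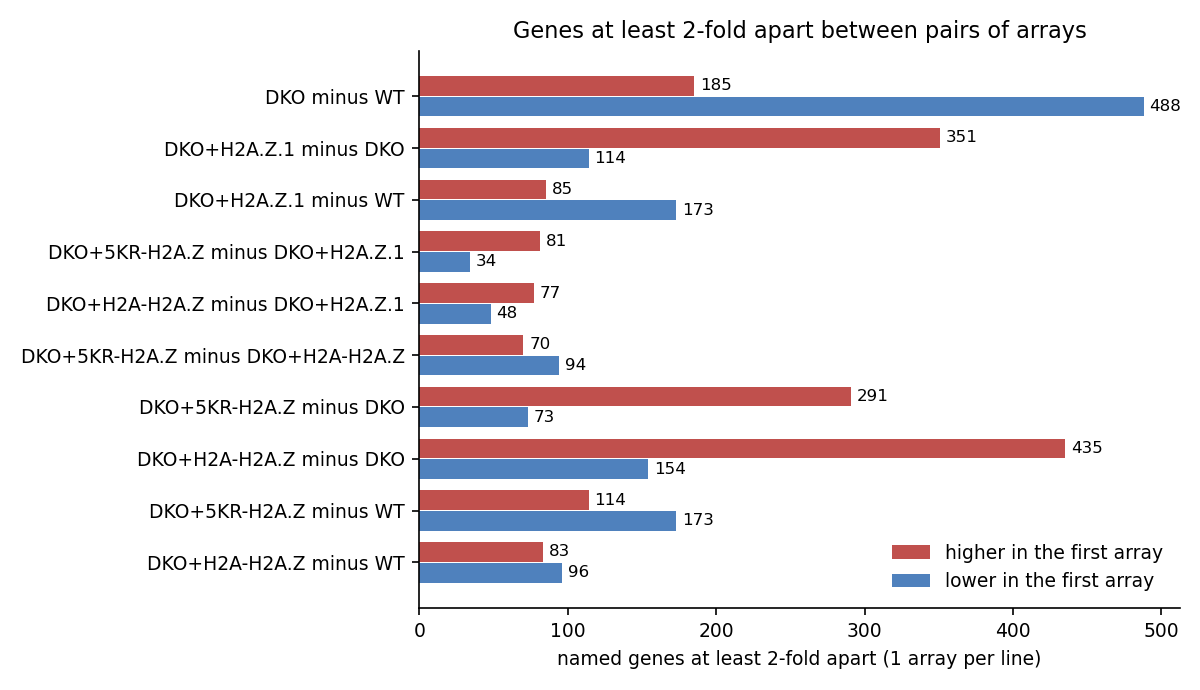
Number of named genes at least 2-fold higher or lower in the first array of each pair (bars, x axis from 0), for the 6 main comparisons and 4 further pairs (y axis), with 1 array per line. The bars for DKO minus WT reach 185 higher and 488 lower, against 81 and 34 for DKO+5KR-H2A.Z minus DKO+H2A.Z.1.

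Loss of H2A.Z was read against both WT and DKO+H2A.Z.1, since DKO and WT also differ in their history as clones. Of 4092 genes with an official symbol well above background on these 3 arrays, 235 were at least 2-fold lower in DKO than in both others and 42 at least 2-fold higher, where simulated unchanged arrays gave 1.27 and 1.02 on average. Both comparisons rest on the same DKO array, so an error of that array beyond the simulated noise would count as agreement. Among the lower genes were SLC11A2, an iron and manganese transporter, -3.70 relative to WT and -3.15 relative to DKO+H2A.Z.1 on the log2 scale, CC2D2A, a protein of the ciliary transition zone (10.5-fold and 8.66-fold lower), and MAVS, the adaptor of cytosolic RNA sensing (7.53-fold and 11.3-fold on the brightest of 4 probes, of which 1 was less than 2-fold lower in each comparison). NME5, CAPN11, PREPL and ALDH4A1, a mitochondrial enzyme of proline breakdown, were 11.8-fold, 10.2-fold, 9.13-fold and 8.55-fold lower than in WT. TMC7, NCF4, a subunit of the phagocyte NADPH oxidase, SERPINB6, JMJD7 and RAB11B, a GTPase of recycling endosomes, were lower than in WT by 6.56-fold to 7.89-fold. HIF1A, the oxygen-regulated transcription factor, was 5.01-fold lower than in WT and 5.84-fold lower than in DKO+H2A.Z.1, with at least 2-fold differences on all 7 of its probes in both comparisons, and HOXA4 was 5.80-fold and 7.54-fold lower.

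On the higher side in DKO stood ENPP2, which makes the lipid mediator lysophosphatidic acid (4.81-fold above WT and 5.03-fold above DKO+H2A.Z.1), PSPH, the last enzyme of serine synthesis (4.97-fold and 4.01-fold), the pro-apoptotic BIK (4.36-fold and 3.89-fold) and the adhesion molecule CDH11 (4.28-fold and 5.02-fold). NPL, an enzyme of sialic acid breakdown, CD200 and SAT1, an enzyme of polyamine breakdown, were 4.56-fold, 4.19-fold and 4.01-fold above WT and 3.75-fold, 2.93-fold and 2.77-fold above DKO+H2A.Z.1. CHAC1, a glutathione-degrading enzyme induced by amino acid stress, was 2.58-fold and 3.20-fold higher, and GPR137B 2.51-fold and 2.78-fold higher on all 5 of its probes. FOS was 3.05-fold above WT on its brighter probe and did not differ on its other probe (-0.02 on the log2 scale).

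**Figure D2:**
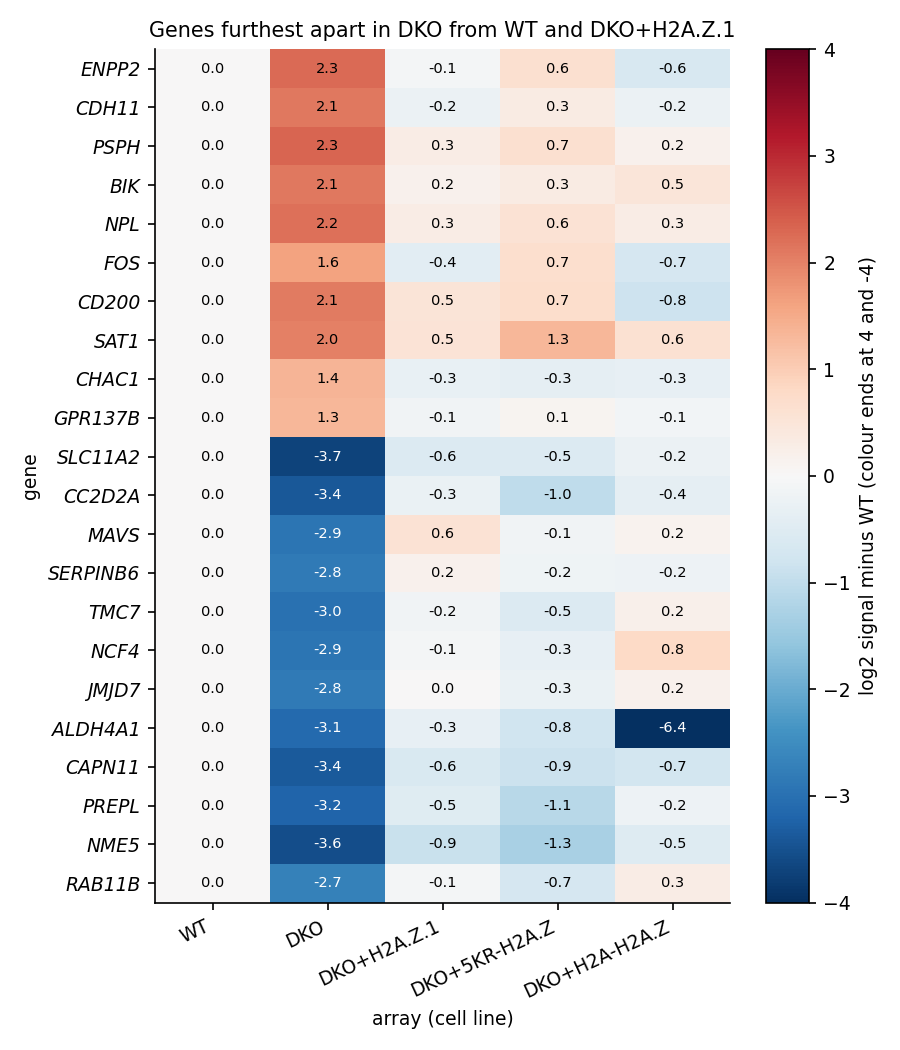
Log2 signal minus that of WT (colour and printed value) for the genes named in the text among those furthest above and furthest below both WT and DKO+H2A.Z.1 in DKO (rows), on the 5 arrays (columns). The DKO column stands apart by construction, and ALDH4A1 is lower still in DKO+H2A-H2A.Z, 67.9-fold below DKO+H2A.Z.1.

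Lower genes in DKO were mostly genes of low or moderate signal: 243 of 1100 genes in the dimmest 25% were at least 2-fold below WT, against 16 of 1100 in the brightest, and genes at least 2-fold above WT were likewise more often dim (82 against 13). The median of all genes was nonetheless 0.15 for DKO minus WT and -0.21 for DKO+H2A.Z.1 minus DKO. The split between higher and lower genes depended on the scaling. Lower genes made up 72.5% of those at least 2-fold apart between DKO and WT, 83.1% in the authors' value table and 91.4% after scaling to the spike-in probes, where the median of all genes was -0.34. For DKO+H2A.Z.1 minus DKO the shares of lower genes were 24.5%, 10.7% and 5.04%.

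Gene lists were read against the median of all genes by the percentile of their own median among 10000 random lists of matched signal. Where a range is given with a median, it is that of the median over the alternatives. The 6 measured immediate early genes had a median of 0.92 for DKO minus WT (percentile 99.99; range 0.16 to 0.96), with JUN 3.08-fold higher and FOS as given above; with no filter on dim probes the median of this list was 0.16, below that of all genes (0.20), at percentile 63.9. Genes of cholesterol synthesis had a median of 0.51 (percentile 99.8, and 96.4 with the median over probes; range 0.01 to 0.55, the lowest after spike-in scaling); 16 of 17 were above 0 and none reached 2-fold. The list of the unfolded protein and amino acid stress response stood at 0.46 (percentile 99.4, and 96.2 with no filter on dim probes and 96.4 with the median over probes; range -0.04 to 0.50, the lowest after spike-in scaling), with PSPH and CHAC1 past 2-fold and 17 of 19 above 0. Ribosomal proteins stood at 0.41 (percentile 98.3), all 45 above 0 and none past 2-fold; after spike-in scaling their median was -0.08, and it was 0.05 after quantile normalization and 0.02 after cyclic loess, against 0.04 and -0.02 over all genes. Their percentile lay within the random lists under 3 alternatives, 94.97 with quantile normalization, 93.3 with cyclic loess and 92.8 with the median over probes. Developmental transcription factors stood at 0.25 (percentile 98.9, and 96.8 with normexp, 83.9 with no filter on dim probes and 83.5 with unmatched random lists; range -0.25 to 0.49, the lowest after spike-in scaling), although 5 of 32, HOXA4 among them, were at least 2-fold lower and 2 at least 2-fold higher.

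Below the random lists for DKO minus WT were the genes of G1/S and DNA replication (median -0.04, percentile 1.40, 23 measured) and those of B cell identity (median -0.02, percentile 2.17, 39 measured), whose medians ranged over -0.54 to 0.04 and -0.51 to 0.03. Several alternatives brought these lists within the random ones: the percentile of the G1/S list was 3.63 with normexp, 2.95 with quantile normalization, 3.07 with cyclic loess, 6.0 with the median over probes and 8.98 with unmatched random lists, and that of B cell identity 17.3 with quantile normalization, 11.1 with cyclic loess, 2.69 with the median over probes and 6.15 with unmatched random lists. DNA repair genes had a median of -0.13 (percentile 4.70, within the random lists), with NBN, a subunit of the break-sensing MRN complex, 5.36-fold, RAD51D 5.21-fold and FANCC 2.77-fold lower in DKO on the brighter of its probes (-0.80 on the log2 scale on the other). Lists that stayed within the random lists included H2A.Z exchange and histone chaperones (median 0.14, percentile 35.1), Polycomb and DNA methylation enzymes (0.17, percentile 63.9), MYC targets and ribosome biogenesis (0.29, percentile 49.3), oxidative phosphorylation (0.32, percentile 49.1), mitosis (0.27, percentile 56.5), heat shock (0.35, percentile 75.3), interferon response (-0.08, percentile 37.8) and apoptosis (0.23, percentile 80.1). In that last list BAK1, which promotes cell death, was 2.17-fold higher (at least 2-fold on 3 of 4 probes, and in 6 of 10 alternative settings) and CASP8 3.31-fold lower. TLR7 and NFKB1 were 3.21-fold and 2.06-fold lower. NFKB1 was past 2-fold in 8 of 10 settings. Over all comparisons, 24 of 156 list values lay outside the central 95% of the random lists, where 7.8 would by chance. Genes of a list may move together and the comparisons share arrays, so the excess is no test of an effect.

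**Figure D3:**
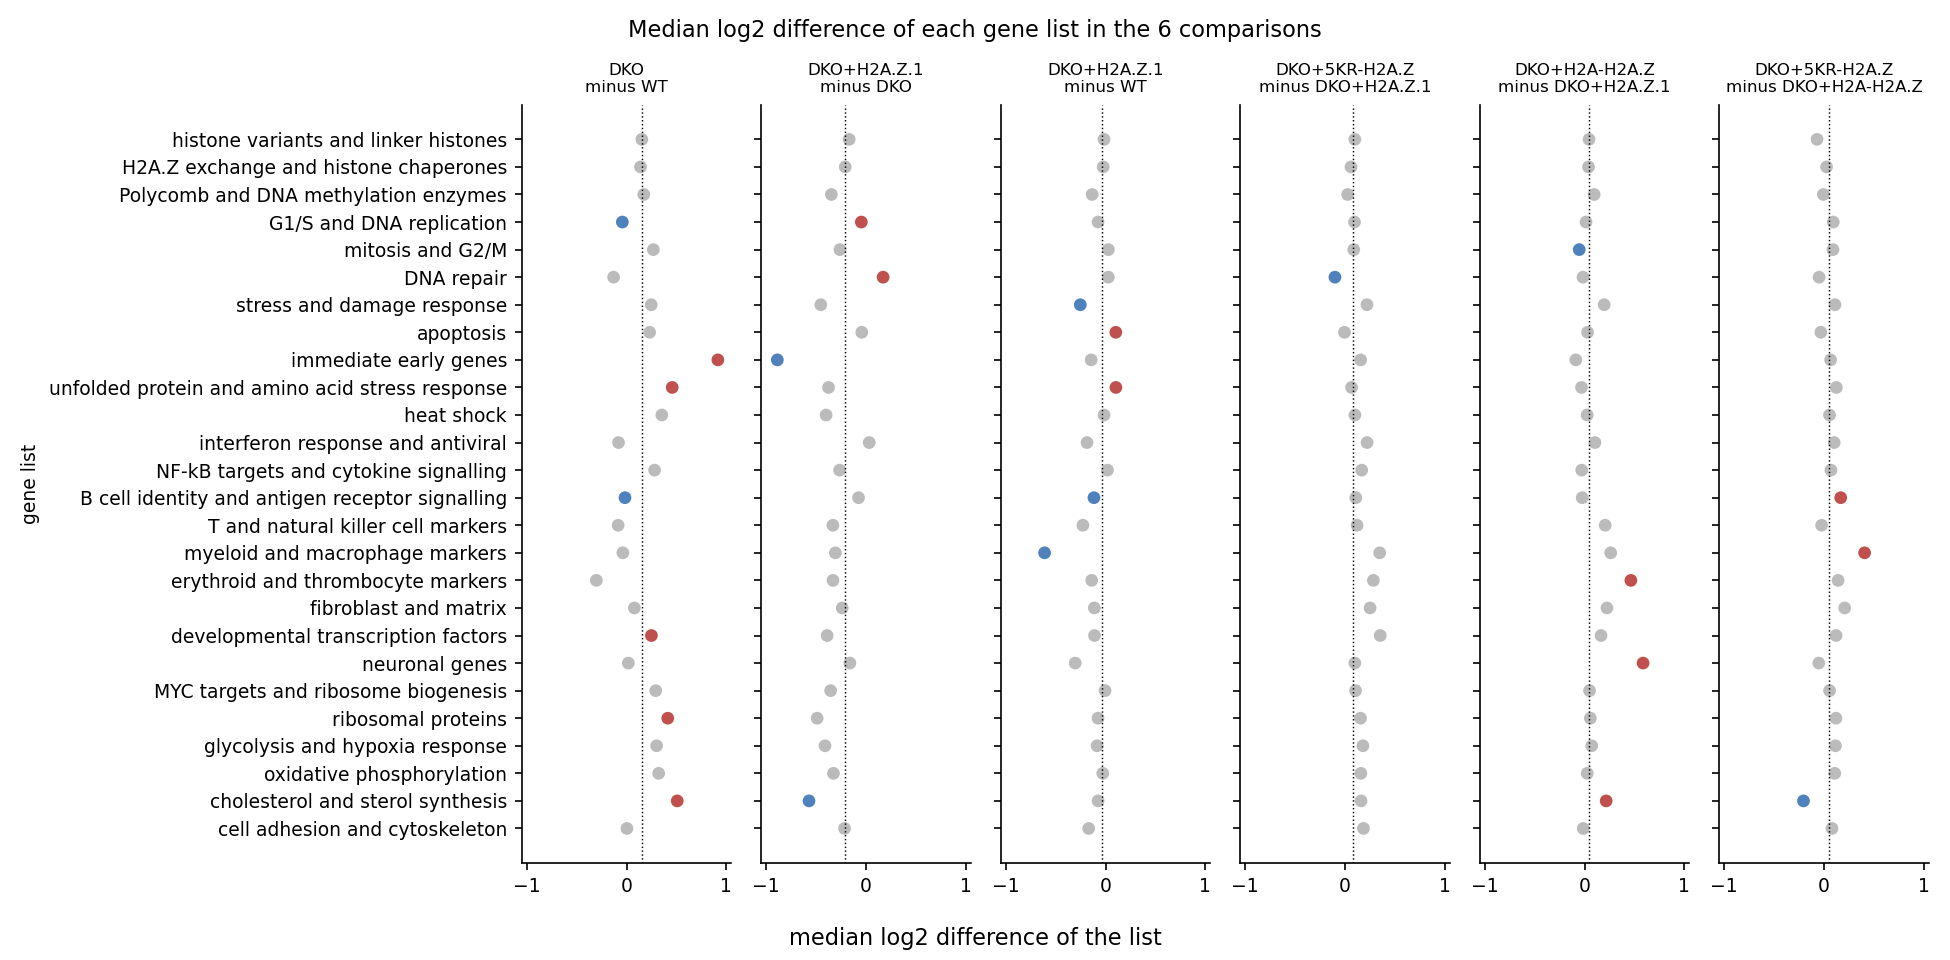
Median log2 difference (x axis) of each gene list with at least 5 measured members (rows) in the 6 comparisons (panels), red above and blue below the central 95% of 10000 random lists of matched signal, grey within; the dotted line is the median of all genes. Cholesterol synthesis stands at 0.51 for DKO minus WT, -0.57 for DKO+H2A.Z.1 minus DKO and 0.22 for DKO+H2A-H2A.Z minus DKO+H2A.Z.1.

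DKO+H2A.Z.1 minus DKO shares the DKO array with DKO minus WT in the opposite sense, which alone makes them run opposite: r was -0.80 and the covariance -0.379 across genes, where simulated unchanged arrays gave -0.50 and -0.0294. All 17 cholesterol synthesis genes lay lower in DKO+H2A.Z.1 than in DKO, none of them 2-fold (median -0.57, percentile 0.01; range -0.61 to -0.03, nearest 0 after spike-in scaling), and the immediate early genes had a median of -0.89 (percentile 0; range -0.93 to -0.34), with FOS 4.09-fold on its brighter probe (-0.01 on the log2 scale on the other), KLF6 2.35-fold and JUN 2.31-fold lower. KLF6 and JUN were past 2-fold in 8 of 10 settings each. The amino acid transporter SLC7A5 was 2.28-fold lower, past 2-fold on 3 of 4 probes and in 6 of 10 settings. DNA repair genes were higher as a list, 3 of 29 past 2-fold (median 0.17, percentile 99.1, and 96.6 with quantile normalization; range 0.13 to 0.72, the highest after spike-in scaling), with NBN 7.29-fold and RAD51D 3.27-fold above DKO, and the G1/S list stood above the random lists with no gene past 2-fold (median -0.05 against -0.21 over all genes, percentile 98.0, and 90.6 with unmatched random lists; range -0.08 to 0.50). CASP8 was 3.21-fold higher. Genes not well above background in DKO included CRADD, an adaptor of cell death signalling (at least 6.31-fold higher in DKO+H2A.Z.1), LGALSL (at least 6.60-fold) and DCLRE1C, the nuclease Artemis (at least 5.13-fold), while MAT1A was at least 9.43-fold lower in DKO+H2A.Z.1, where it was not well above background. Over the alternatives the smallest differences were 0.66 for CRADD, 0.76 for LGALSL, 0.51 for DCLRE1C and 1.30 for MAT1A in size on the log2 scale.

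Of the 673 genes at least 2-fold apart between DKO and WT, 451 lay nearer to WT than to DKO in DKO+H2A.Z.1 (67.0%, 95% Wilson interval 63.4 to 70.5, which covers the number of genes alone). The share was 413 of 672 in DKO+5KR-H2A.Z (61.5%, 57.7 to 65.1) and 540 of 673 in DKO+H2A-H2A.Z (80.2%, 77.1 to 83.1), both placed across slides. A simulated line equal to DKO apart from noise gave 2.41%. It was centred on the measured DKO level, which also picked the genes. The simulation therefore leaves out the shift towards WT that this choice brings, and 2.41% is too low as a reference. Where DKO and WT do not differ, 38.5 genes on average were picked by noise in simulations, and 49.2% of them (at most 69.4%) counted as restored in an unchanged line. Genes that part WT from every line made from the DKO count as not restored here. Among the 355 genes apart in the same direction from both WT and DKO+H2A.Z.1, 306 were restored in DKO+5KR-H2A.Z (86.2%) and 337 in DKO+H2A-H2A.Z (94.9%). Simulated unchanged arrays gave 8.51 such genes on average, of which 63.4% counted as restored in an unchanged line. A simulated line equal to DKO, centred in the same way, gave 1.75%. An error of the DKO array would raise the shares of the real lines but not this one. On a scale from 0 at DKO to 1 at the mean of WT and DKO+H2A.Z.1, their median position was 0.79 in DKO+5KR-H2A.Z and 1.01 in DKO+H2A-H2A.Z, across slides. With the threshold that a gene come within 1.5-fold of WT, the shares for the 3 lines in the order above were 56.6%, 46.7% and 67.0%.

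DKO+H2A.Z.1 and DKO shared some of their distance from WT: 35 genes were at least 2-fold higher and 57 at least 2-fold lower in both, where simulated unchanged arrays that share WT gave 2.34 in all. The covariance across genes was 0.196 (simulated 0.0298) and r = 0.57 (simulated 0.50). The sulfurtransferase gene TST was 88.1-fold higher, and MPST, a sulfurtransferase gene next to it on the chromosome, at least 229-fold higher than in WT, where it was not well above background. RGS20, a regulator of G protein signalling, MAPK11, a p38 kinase, and LITAF were 5.02, 4.65 and 4.55 higher on the log2 scale, and MAL2 at least 44.1-fold. IRF4, a transcription factor of B cells, was 2.24-fold higher and CD3E, a chain of the T cell receptor complex, 10.6-fold on the brighter of 2 probes and 0.78 on the log2 scale on the other. ANXA5 and COL1A2 were 6.16-fold and 4.88-fold higher, COL1A2 with 1 of 4 probes under 2-fold. Besides H2AFZ, lower genes were OAF (44.5-fold), the elongation factor ELL2 (18.5-fold), DCX (10.8-fold), COL20A1 (8.87-fold) and, below background in DKO+H2A.Z.1, the adhesion molecule CDH2 (at least 19.1-fold).

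Among lists, myeloid markers were lower in DKO+H2A.Z.1 than in WT (median -0.61, percentile 0.230, and 9.57 with no filter on dim probes; range -0.61 to -0.23; 4 of 14 at least 2-fold lower), with TLR4 4.10-fold, IL18 3.27-fold and the protease CTSS 2.12-fold lower. IL18 was past 2-fold in 8 of 10 settings. Expression of these genes is not confined to myeloid cells. The list of B cell identity (median -0.12, percentile 1.97, but 2.93 with quantile normalization, 18.1 with the median over probes and 3.19 with unmatched random lists) and that of stress and damage response (median -0.25, percentile 1.00, but 6.01 with normexp, 7.27 with no filter on dim probes and 4.90 with the median over probes) were lower, the latter with DDB2 2.29-fold (on the brighter of its probes, -0.11 on the log2 scale on the other) and GADD45G 2.26-fold down. The lists of apoptosis (median 0.10, percentile 97.7, but 83.98 with normexp, 93.1 with every array above background and 95.7 with the median over probes) and of the unfolded protein response (median 0.10, percentile 99.4, but 93.3 with the median over probes) lay slightly above the random lists, with 1 gene of the first past 2-fold each way and none of the second. Within the first, BCL2, which blocks apoptosis, was 2.22-fold lower. Neuronal genes (median -0.30, percentile 13.4) and markers of fibroblasts (-0.11, percentile 48.3) did not stand apart. Of the 258 genes at least 2-fold apart, 145 were well above background on both arrays.

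DKO+5KR-H2A.Z was compared with DKO+H2A.Z.1, across slides. EEF1A2, a translation elongation factor, was 3.24-fold higher, RNP 3.64-fold, the activin antagonist FST 3.05-fold, TENM2 2.94-fold and the alpha globin HBA1 3.53-fold. Of these, EEF1A2, TENM2 and HBA1 were also higher in DKO+H2A-H2A.Z than in DKO+H2A.Z.1, so they are not particular to this mutant. Among genes well above background on all arrays, 12 were at least 2-fold higher and 0 lower in both mutant lines. Simulated unchanged arrays that share DKO+H2A.Z.1 gave 2.04 in all. LAMB4, a laminin chain, was at least 10.1-fold higher, MPZL2 at least 7.84-fold and CHAT, the enzyme of acetylcholine synthesis, at least 5.63-fold, each from below background in DKO+H2A.Z.1. Over the alternatives the smallest difference for CHAT was 0.86 on the log2 scale. Lower genes were MND1, a factor of meiotic recombination (2.61-fold), LMO2 (2.41-fold), PLOD1, a collagen lysine hydroxylase (2.32-fold), SMCO4 (2.33-fold), DTWD2 (2.11-fold) and GSTZ1 (2.00-fold). DNA repair was the 1 list outside the random lists, with 23 of 29 genes lower and none past 2-fold (median -0.10, percentile 0.06; range -0.37 to -0.09). Cholesterol synthesis (0.16, percentile 85.6), B cell identity (0.11, percentile 73.0) and H2A.Z exchange (0.06, percentile 39.2) lay within them. Of the 115 genes at least 2-fold apart 57 were well above background on both arrays, and lower genes made up 29.6% of the 115, 41.4% after cyclic loess and 59.0% after spike-in scaling.

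DKO+H2A-H2A.Z differed from DKO+H2A.Z.1 in a few genes by large factors. ALDH4A1 was 67.9-fold lower on its single probe, FABP5, a fatty acid binding protein, 18.5-fold, NAV3 16.2-fold, MAL2 9.48-fold and the organic anion transporter SLCO4A1 8.60-fold, the last with 1 of 5 probes under 2-fold (-0.81 on the log2 scale). OAF was 31.4-fold higher, APP, the amyloid precursor protein, 3.52 on the log2 scale, the B and T cell surface protein CD5 10.2-fold on its brighter probe (and 0.30 on the log2 scale on the other), ELL2 5.34-fold and TENM2 4.96-fold, with CDH2 at least 7.74-fold higher. For FABP5, NAV3, MAL2, OAF, APP, CD5 and ELL2 this difference ran towards WT. IRF4 was 2.04-fold lower. The list of cholesterol synthesis lay above the random lists (median 0.22, percentile 100; range 0.18 to 0.25), with 16 of 17 genes above 0 and none past 2-fold. The list of mitosis lay below them (median -0.05, percentile 0.150, but 14.8 with normexp), none past 2-fold either. Erythroid markers (median 0.46, percentile 98.6, but 90.6 with the median over probes; range 0.27 to 0.47; with HBBA 2.32-fold and HBA1 2.15-fold higher, past 2-fold in 8 of 10 and 7 of 10 settings) and neuronal genes (median 0.59, percentile 98.9) also lay above the random lists. The median of the neuronal list was 0.19 with normexp (percentile 94.2) and 0.18 with no filter on dim probes (percentile 69.5), both within the random lists. Of the 125 genes at least 2-fold apart, 61 were well above background on both arrays.

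The mutant lines shared a slide and were compared directly. In DKO+5KR-H2A.Z, ALDH4A1 was 48.7-fold, FABP5 28.8-fold, MAL2 16.2-fold, SLCO4A1 8.99-fold, FAM26E 4.15-fold and the potassium channel subunit KCNMB1 4.06-fold higher than in DKO+H2A-H2A.Z; 1 of 5 probes of SLCO4A1 and 1 of 3 of FAM26E lay under 2-fold (0.75 and 0.99 on the log2 scale). OAF was at least 47.0-fold lower, APP 5.77-fold, LMO2 4.93-fold, PLOD1 4.06-fold, the inhibitory receptor LAG3 3.89-fold, EPM2A, a glycogen phosphatase, 3.60-fold and RAD51D 2.00-fold. RAD51D was past 2-fold in 8 of 10 settings. The list of cholesterol synthesis lay below the random lists in DKO+5KR-H2A.Z, with 13 of 17 genes below 0 and none past 2-fold (median -0.21, percentile 0; range -0.45 to -0.15). The lists of B cell identity (median 0.17, percentile 99.8; range -0.07 to 0.18, below 0 only after spike-in scaling) and myeloid markers (median 0.41, percentile 99.9, but 81.7 with the median over probes; range 0.16 to 0.41) lay above the random lists. Among myeloid markers 1 gene was past 2-fold each way, CEBPA 2.05-fold higher and TLR4 2.57-fold lower (in 8 of 10 settings each). Lower genes made up 57.3% of the 164 genes at least 2-fold apart and 75.2% after spike-in scaling.

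Across the 4110 genes well above background on all arrays, the difference between the mutant lines followed the difference between DKO and WT (Pearson r = 0.49 across genes, which are not independent replicates). These differences share no array and each lies within a slide. Simulated unchanged arrays gave 0, as their noise was independent by construction. Of the genes past 2-fold in both, 22 were higher in both and 29 lower in both, where independent lists would share 1.33 and 3.63. Neither reference shows how far unrelated cultures would be alike. For comparisons that share DKO+H2A.Z.1, part of any likeness comes from that array: DKO and DKO+5KR-H2A.Z, each relative to it, gave r = 0.51 and a covariance of 0.0960 (simulated unchanged arrays r = 0.50, covariance 0.0295), DKO and DKO+H2A-H2A.Z gave r = 0.04 and a covariance of 0.00770, and the mutant lines gave r = 0.34 and a covariance of 0.0344. Against DKO minus WT, with no shared array, the mutant lines relative to DKO+H2A.Z.1 gave r = 0.27 for DKO+5KR-H2A.Z and -0.29 for DKO+H2A-H2A.Z.

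**Figure D4:**
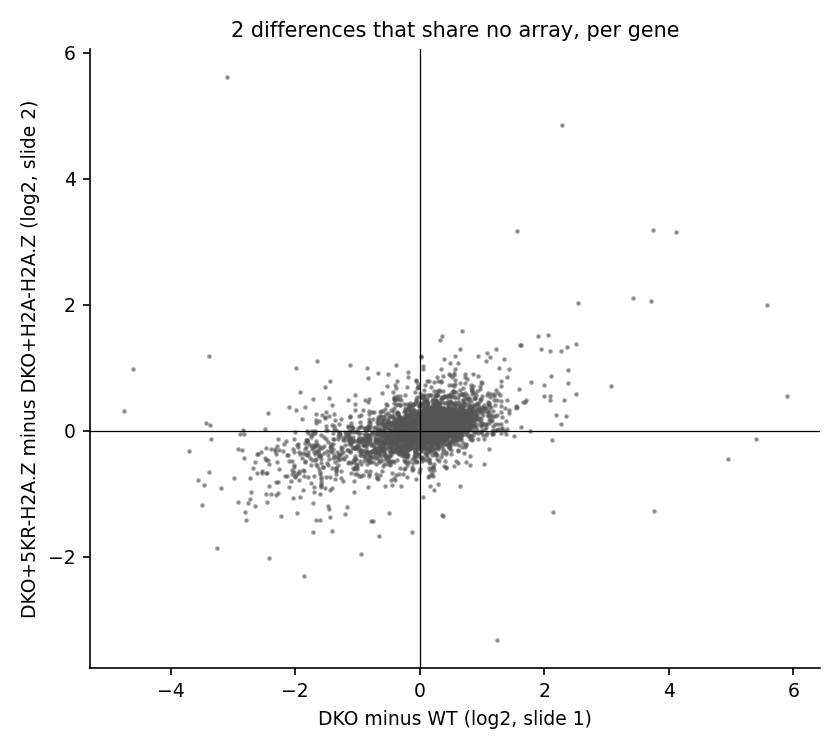
Log2 difference between DKO and WT (x axis) and between DKO+5KR-H2A.Z and DKO+H2A-H2A.Z (y axis) for 4110 genes (points) well above background on all 5 arrays. The differences share no array, and r across genes is 0.49.

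The planned split by intact H2A.Z set WT and DKO+H2A.Z.1 against the other 3 arrays and parted 51 genes, with no overlap between the sides and means at least 2-fold apart. Of those, EEF1A2 was higher in the 3 arrays, EPHX2, an epoxide hydrolase, was lower (at least 3.04-fold in DKO+H2A-H2A.Z than in DKO+H2A.Z.1), and ANKRD22 was at least 5.94-fold lower in DKO+H2A.Z.1 than in DKO. Over the alternatives the smallest of these differences was 0.23 in size for EPHX2 and 0.97 for ANKRD22 on the log2 scale. Most of the 51 genes are dim: 13 of the kind were found among genes well above background on all arrays. DKO and DKO+5KR-H2A.Z were parted from the other 3 arrays by 209 genes and WT and DKO+H2A-H2A.Z by 170, while the other splits gave between 34, for the split between the slides, and 83. Every split sets arrays of different slides against each other. The arrays closest to each other by median absolute difference were DKO+H2A-H2A.Z and DKO+H2A.Z.1 (0.138 on the log2 scale), and the furthest apart DKO and WT (0.376). By Pearson r the closest were DKO+5KR-H2A.Z and DKO+H2A.Z.1 (0.9958, against 0.9949 for DKO+H2A-H2A.Z and DKO+H2A.Z.1).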

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

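LMO2, a transcriptional partner protein of blood cell development, was the 1 gene among those fixed by the rule that moved at least 2-fold one way in a mutant line and at least 2-fold the other way in the other, relative to DKO+H2A.Z.1, with all 3 arrays well above background. It was 2.41-fold lower in DKO+5KR-H2A.Z and 2.04-fold higher in DKO+H2A-H2A.Z, and DKO+5KR-H2A.Z minus DKO+H2A-H2A.Z, within a slide, was -2.30 on the log2 scale. Over 10 settings LMO2 stayed past 2-fold in 9 for DKO+5KR-H2A.Z (smallest size 0.49 on the log2 scale), in 7 for DKO+H2A-H2A.Z (smallest 0.61) and in 10 between the mutant lines (smallest 1.095). The difference was not tested and no explanation for it was, since each line has 1 array, and it rests on a single probe. LMO2 was 4.90-fold lower in DKO+H2A.Z.1 than in WT, so that in DKO+H2A-H2A.Z, on another slide than both, it lay nearer to WT.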

How the results depend on the processing

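No paired analysis was possible because each line has 1 array, and leaving out replicates or adding a slide term was not possible for that reason. Spike-in scaling and leaving out the genes of the chromosome that carries TK2 were chosen after the data were seen; the latter gave 643 genes for DKO minus WT. Counts of genes at least 2-fold apart, given in the order DKO minus WT, DKO+H2A.Z.1 minus DKO, DKO+H2A.Z.1 minus WT, DKO+5KR-H2A.Z minus DKO+H2A.Z.1, DKO+H2A-H2A.Z minus DKO+H2A.Z.1 and DKO+5KR-H2A.Z minus DKO+H2A-H2A.Z, moved from 673, 465, 258, 115, 125 and 164 to 379, 242, 97, 17, 36 and 45 with normexp, to 1377, 1139, 565, 410, 381 and 434 at 1.5-fold and to 353, 200, 152, 45, 58 and 75 at 3-fold, these last as a matter of the threshold itself. Requiring every array compared to be well above background gave 145, 57, 61 and 93 for the last 4, and no filter on dim probes 389, 228, 239 and 291, since the filter sets how many dim genes are counted. Spike-in scaling gave 754 for DKO+H2A.Z.1 minus DKO, as it shifts every gene of an array by 1 amount. The share restored in DKO+H2A.Z.1, 67.0%, was 74.4% with normexp, 73.9% with every array above background, 74.5% with spike-in scaling, 72.9% and 62.3% at 1.5-fold and 3-fold, and 56.6% when within 1.5-fold of WT was asked. In DKO+5KR-H2A.Z, 61.5% became 69.5% with every array above background, 65.2% in the authors' value table, 56.2% at 3-fold, 46.7% within 1.5-fold of WT and 86.2% for genes apart from both references. In DKO+H2A-H2A.Z, 80.2% became 86.0% with normexp, 87.9% with every array above background, 74.3% with no filter, 86.4% with spike-in scaling, 75.6% at 3-fold, 67.0% within 1.5-fold of WT and 94.9% for genes apart from both references. The 51 genes of the split by intact H2A.Z became 11 with normexp, 13 with every array above background and 140 at 1.5-fold. Of the 24 list values outside the random lists, 13 stayed so on the same side with the median over a gene's probes and 18 to 24 under the other alternatives. DKO and DKO+5KR-H2A.Z gave the most genes of the 10 splits in each of the 11 settings run at 2-fold, from 84 to 369. Apart from the counts that follow from the filter, the threshold or the scaling as said, the cause was not tested. Of 189 differences of genes named in the text, each counted once, 187 stayed past 2-fold in the same direction after cyclic loess, 184 in the authors' value table, 177 with spike-in scaling, 165 with the median over a gene's probes and 149 with normexp. The direction reversed for AMIGO2 in DKO+5KR-H2A.Z minus DKO+H2A.Z.1, from 1.77 on the log2 scale (at least 2.10-fold) to -0.37 with the median over a gene's probes. AMIGO2 was past 2-fold there in 7 of 9 alternative settings, and the cause was not tested. The counts under the filters show how far weak signal limits these results.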

Other observations

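The split by intact H2A.Z and the scalings other than spike-in scaling were planned; the tests that use them below, and the other tests in this part, were chosen after the results they bear on had been seen. Singled out against all 4 other arrays at 2-fold, DKO had 216 genes lower and 33 higher, WT 33 lower and 63 higher, DKO+H2A.Z.1 9 and 7, DKO+5KR-H2A.Z 9 and 13, and DKO+H2A-H2A.Z 12 and 17, each count taken over arrays of both slides. Neighbouring genes sometimes moved as a block. The 15 measured genes from MRPL33 to YIPF4, around POLH, which encodes a DNA polymerase that copies past damage, were all lower in DKO+H2A.Z.1 than in WT (median -0.54, where the lowest of 100 random gene orders gave -0.42). In DKO their median was -0.59, within what random orders gave (down to -1.24). Across slides it was -0.68 in DKO+5KR-H2A.Z (random orders down to -0.61) and -0.10 in DKO+H2A-H2A.Z. From SCCPDH to TBP, 14 of 15 genes were higher in DKO+H2A-H2A.Z than in DKO+H2A.Z.1, across slides (median 0.60, random orders at most 0.42). Relative to WT this block stood within a slide at -0.47 in DKO+H2A.Z.1, beyond the random orders, and -0.14 in DKO, within them, and across slides at -0.48 in DKO+5KR-H2A.Z, within them, and 0.00 in DKO+H2A-H2A.Z. From EIF2AK2 to ACTN2, 14 of 15 genes were lower in DKO+5KR-H2A.Z than in DKO+H2A-H2A.Z, within a slide (median -0.64, random orders down to -0.47). Relative to WT this stretch stood within a slide at -0.28 in DKO and -0.50 in DKO+H2A.Z.1. Across slides it stood at -0.54 in DKO+5KR-H2A.Z and 0.01 in DKO+H2A-H2A.Z.

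The 1st pattern is that DKO+5KR-H2A.Z lay nearer to DKO than DKO+H2A-H2A.Z did. For this the tables argue against a difference between the slides or an intensity trend, as the difference between the mutant lines followed DKO minus WT with r = 0.49 without a shared array or slide, and with r = 0.49 after cyclic loess (0.44 to 0.53 over all settings, of which those with 1 factor per array cannot move it). Whether DKO+5KR-H2A.Z also lay nearer to DKO than DKO+H2A.Z.1 did cannot be told apart from a slide effect: relative to DKO+H2A.Z.1, r was 0.27 for DKO+5KR-H2A.Z and -0.29 for DKO+H2A-H2A.Z, and part of the difference between the mutant lines may come from DKO+H2A-H2A.Z lying further from DKO. A fixed share of RNA from cells like DKO stays open. The median share needed was 29.6% for genes lower in DKO and 17.1% for genes higher, 12.5 percentage points apart. The ranges over single genes overlapped, which cannot decide whether the medians differ. The SE of 4.02 on the difference between the medians covers the number of genes alone, with 1 array behind each line. Less RNA or weaker labelling stays open too, as the 75th percentile relative to the spike-in was -0.24 in DKO+5KR-H2A.Z and -0.52 in DKO relative to the mean of the other 3 arrays, although r did not drop after cyclic loess as it would if this acted through an intensity trend alone. A difference in function between the mutant proteins is an untested biological explanation, and the one that the design names. Differences between the lines as clones, as in the block from EIF2AK2 to ACTN2, were not tested and stay open as well.

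The 2nd pattern is that more genes were lower than higher in DKO. The tables argue against scaling, because at least 69.2% (at most 91.4%) of the genes at least 2-fold apart from WT were lower under every scaling run. Weaker signal of the whole array was tested on the spike-in probes, of which the lowest in DKO relative to WT stood at -0.12 and the highest at 0.18. Of the lower genes, 71.9% lie in the range of brightness of these probes. The spike-in probes do not test the amount of sample RNA. Relative to them the 75th percentile was -2.21 in DKO and -1.71 in WT on the log2 scale, so less RNA or weaker labelling stays open here too. RNA quality was not tested, and loss of H2A.Z is the biological explanation that the design names, with 1 array behind it.

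The 3rd pattern is a chromosome, the one that carries TK2, whose 129 measured genes were lower as a group than in WT in every line made from the DKO, with medians relative to all genes of -0.36 in DKO, -0.35 in DKO+H2A.Z.1, -0.39 in DKO+5KR-H2A.Z and -0.42 in DKO+H2A-H2A.Z. In these comparisons 29 other chromosomes lay between -0.12 and 0.12. All of these medians use the same WT array, so they do not repeat each other. In the comparisons run between the lines made from the DKO, the chromosome stood between -0.0324 and 0.0046. The tables argue against a difference between the slides, with a shift of -0.35 or beyond within a slide, and against dim genes, since the brightest genes of the chromosome shifted by -0.36 or beyond relative to other genes in their range of signal; this measure replaced an earlier one, not matched on signal, whose weakest shift was -0.22. Fewer copies of the chromosome than in WT may explain it and stay open, and whether WT or the other lines changed cannot be told: 69.8% of its genes lay below the median of all genes in DKO and up to 81.4% in the other lines. The lines made from the DKO would then differ from WT in more than H2A.Z.

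A further hypothesis was that intact H2A.Z is the main axis of the 5 arrays. The split that sets WT and DKO+H2A.Z.1 apart gave 51 genes, and 6 of the 10 splits of the arrays into 2 and 3, itself included, gave as many or more, with 209 at most for DKO and DKO+5KR-H2A.Z. The hypothesis was not borne out, and the splits are too few for a share under 0.05.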
